A study of Drosophila melanogaster with 12 samples.

How the data were processed

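The 12 libraries came from Drosophila melanogaster S2 cells in 4 groups of 3: untreated cells, and cells given dsRNA against row, BEAF-32 or both. Per the labels' protocols, dsRNA was added at 4 µg per ml of cells and again at 8 µg per ml after 2 days, and cells were collected 2 days later. Untreated cells received no dsRNA, so no group measured the response to dsRNA of unrelated sequence. Libraries were made, per the labels' protocols, from 100 ng of RNA with oligo-dT primers that carried a 7-base sample barcode and an 8-base molecular identifier, pooled, and fragmented with Tn5 transposase. Per the submitters' processing notes, reads were aligned with STAR to the build dm3, with no version given. The annotation, the counting step, the use of strand and the handling of molecular identifiers are not given in the sources used here. The 8-base identifier has 65536 forms, and 5 values of 1 gene exceeded that number.

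The authors deposited raw counts per gene, 1 column per library, not normalized. The table held 16718 genes, of which 5628 had 0 counts in every library, and no summary entries. Columns were tied to samples by their names, and groups were taken from the labels. Total counts ran from 2276507 to 3963412 per library. Gene symbols, chromosome arms and strands are those of the count table. Of its symbols 16567 matched the reference annotation BDGP6.54 (12672 by name and 3895 by synonym). That is another build than the one named by the submitters, so it served for names and neighbours and no coordinates are printed. Of the 42 genes called in any comparison, 27 overlap another annotated gene, and their counts are uncertain to that extent.

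The tests of the comparisons and of the gene lists, the lists themselves, the alternatives and the rule for named genes were fixed before the data were examined. Some tests of explanations were chosen later, and the closing section names them. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (minimum count 10), scaled by TMM (factors 0.962 to 1.05). They were fitted with a robust quasi-likelihood model over all 12 libraries with no block, which left 8 residual degrees of freedom. The tests added prior degrees of freedom estimated over genes (median 51.4). The 7 comparisons were each dsRNA group against control, the dsRNA groups against each other, and the interaction on the log2 scale. P-values were adjusted by the Benjamini-Hochberg method over the 7377 tested genes with a threshold of 0.05. CPM values use TMM-scaled totals and are given as mean ± SD of 3 libraries. SE is a standard error of the log2 fold change derived from the test: its absolute value over the square root of F. With 3 libraries against 3, 10% of unchanged genes have groups that do not overlap; the observed share was 10.2% to 13.2%, and the groups of every called gene did not overlap.

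Gene lists (33, fixed in advance) covered chromatin and insulator partners, stress, immunity, metabolism, cell cycle, cell type markers and ribosomes. Of these 28 were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, 4 had fewer than 3 tested members, and 1 matched no symbol in the table. Adjustment ran over 196 tests (28 lists in 7 comparisons). Of the 20 calls so made, 0 held with the correlation estimated from these libraries or in fry. The genes named were row and BEAF-32, and for each comparison with control up to 8 in each direction (up to 4 in the others) with the largest log2 change among those past the threshold. These also had a mean CPM of at least 10 and groups that did not overlap. Added to them were up to 4 members per described list (up to 2 where none passed) and genes changed in all 3 comparisons with control. Other names are stated as such where they occur.

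Alternatives were DESeq2's size factors in edgeR, library totals alone, no filter on low counts, CPM of at least 10 in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a replicate block, only the groups compared, a threshold of 0.01, and leaving out each library in turn. The gene test was checked on simulated data with 50 genes changed at each fold. For BEAF-32 RNAi against control (7248 genes) it recovered 34% of genes changed 1.5-fold, 64% changed 2-fold and 86% changed 3-fold. The shares were 28%, 60% and 84% for row RNAi (7237 genes), 32%, 60% and 72% for double RNAi (7241 genes), and 16%, 48% and 54% for the interaction. Changes of 1.25-fold were recovered in 2%, 6%, 8% and 0%. All these changes were made in 1 group at once. The simulated comparisons with control so had 101, 92 and 89 calls, 8, 3 and 3 of them unchanged genes. The real ones had 2, 14 and 20 calls. The Benjamini-Hochberg cut-off loosens with the number of calls, so the shares overstate recovery where few genes change. Of 40 unchanged lists per comparison with control, 1, 1 and 0 had camera p under 0.05. Genes were simulated independently, so this check could not show false list calls that come from correlation between genes.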

Results

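Gene expression was measured in Drosophila S2 cells, an embryo-derived line with macrophage-like properties, by 3' RNA-seq. The assay counts transcripts from their polyadenylated ends. The cells were untreated (control) or had received double-stranded RNA (dsRNA), which triggers RNA interference (RNAi), against row, against BEAF-32, or against both (double RNAi), with 3 libraries in each of the 4 groups. ROW is a zinc finger protein of the HP1c chromatin complex, and BEAF-32 is a DNA-binding insulator protein. The series title names their joint role in regulating genes over long range. Total counts ran from 2276507 (double RNAi replicate 1) to 3963412 (double RNAi replicate 3), and 8574 to 9107 of the 16718 genes in the table had a count in a library. After the filter on low counts 7377 genes were tested, with a common biological coefficient of variation of 0.172. Pairs of libraries within a group correlated across genes at 0.950 to 0.962 and pairs between groups at 0.943 to 0.965. Chi-square per degree of freedom between libraries of a group was 3.71 to 6.42, which does not show separate samples, since the counts may include amplified copies of a molecule. On principal component 1, with 12.7% of the variance, BEAF-32 RNAi replicate 3 (25.5) and control replicate 1 (-23.4) stood farthest apart. On principal component 2, with 12.1%, the 6 row RNAi and double RNAi libraries lay at 6.70 to 22.1 and the 6 control and BEAF-32 RNAi libraries at -18.0 to -0.32. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

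The RNAi targets were lower in the libraries treated against them. BEAF-32, on chromosome arm 2R, averaged 57.2 ± 12.6 CPM (counts scaled to a common library total; SD, n = 3) in control and 21.0 ± 5.31 in BEAF-32 RNAi (36.7% of control). It averaged 29.9 ± 3.59 in double RNAi (52.3%) and 59.2 ± 7.25 in row RNAi (103%). It fell by 1.44 on the log2 scale in BEAF-32 RNAi (SE 0.22, adjusted p = 1.77e-04) and by 0.93 in double RNAi (SE 0.22, adjusted p = 0.0322). Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The row transcript, also on 2R, averaged 50.7 ± 3.04 CPM in control and 26.2 ± 5.99 in row RNAi (51.7% of control), where it fell by 0.95 (SE 0.22, adjusted p = 0.0379). In double RNAi row averaged 31.4 ± 5.15 CPM (61.9% of control), a log2 change of -0.71 (SE 0.22) with adjusted p = 0.202 over all genes. Adjusted over row and BEAF-32 alone its p was 0.00213, the same as its unadjusted p. Row in BEAF-32 RNAi (41.9 ± 5.05 CPM, log2 change -0.27, adjusted p = 0.978) and BEAF-32 in row RNAi (log2 change 0.05, adjusted p = 0.997) did not pass. The BEAF-32 call in BEAF-32 RNAi held whichever of the 6 libraries was left out (highest adjusted p = 0.0136). The row call in row RNAi was lost without control replicate 1, 2 or 3 or row RNAi replicate 1 or 3 (highest adjusted p = 0.306). The BEAF-32 call in double RNAi was lost without control replicate 1 or 3 or double RNAi replicate 1, 2 or 3 (highest 0.243). It was also lost with library totals alone (0.0604) and in limma-voom (0.0512).

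**Figure D1:**
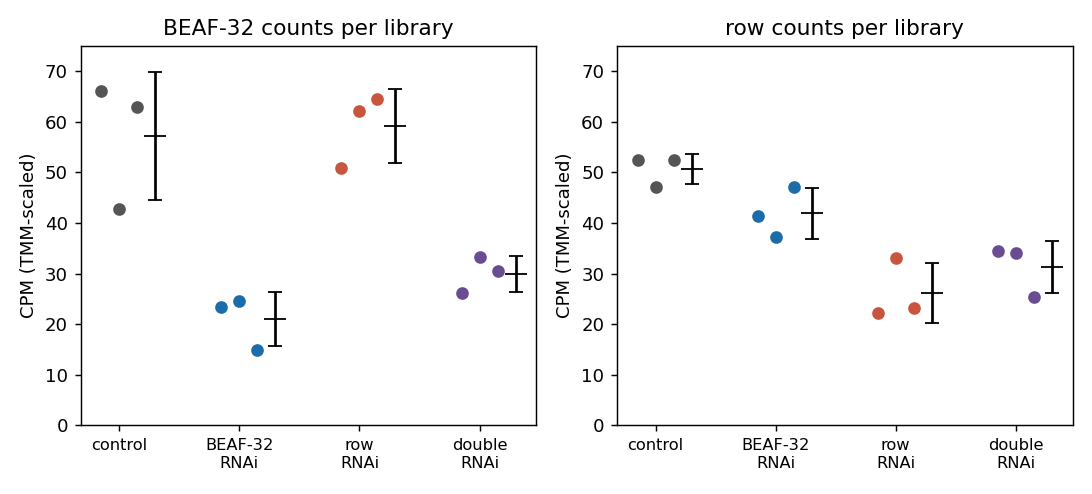
BEAF-32 (left) and row (right) in CPM, scaled by TMM, in each library (points), with the mean and SD of the 3 libraries of each group (bar to the right of the points). BEAF-32 averaged 57.2 in control, 21.0 in BEAF-32 RNAi and 29.9 in double RNAi, and row averaged 50.7 in control, 26.2 in row RNAi and 31.4 in double RNAi.

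BEAF-32 RNAi against control asked which transcripts change in cells given dsRNA against BEAF-32. These libraries measure transcripts, so depletion of the proteins was not measured. Besides BEAF-32 itself, CG4210 on 3R changed: it averaged 41.8 ± 9.03 CPM in control and 14.5 ± 6.29 in BEAF-32 RNAi (SD, n = 3 each), a fall of 2.84-fold (log2 change -1.51, SE 0.28, adjusted p = 0.00525). Cell cycle and DNA replication genes were lower as a list, with 36 of 45 measured members below 0 and a median log2 change of -0.16 (camera adjusted p = 0.0134). This call was lost with an estimated correlation (adjusted p = 0.656 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Among those members the mitotic cyclins CycA and CycB3 had log2 changes of -0.34 (SE 0.16) and -0.58 (SE 0.27), the mitotic kinase aurB -0.35 (SE 0.15) and DNApol-delta -0.33 (SE 0.15). All 6 measured lamellocyte markers, genes of an activated blood cell type, lay above 0 with a median of 0.32, but the list did not pass (camera adjusted p = 0.0569), with 0 members past the test over all genes and 2 adjusted over the list alone. In all, 0 genes were higher and 2 lower in edgeR, and DESeq2 and limma-voom also called 2. An unadjusted p under 0.05 was reached by 382 genes, where chance gives 369. Without BEAF-32 RNAi replicate 3, which stood apart on principal component 1, the cell cycle list had adjusted p = 0.312, and 0.126 without control replicate 3. CG4210 was lost without control replicate 3 or BEAF-32 RNAi replicate 1 or 3 (highest adjusted p = 0.348), leaving 1 call. Without control replicate 2, 4 genes passed. CG4210 overlaps SIDL on the opposite strand, and whether counting used strand is not given in the sources used here.

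Row RNAi against control asked the same of dsRNA against row. CG15209 on the X fell 4.62-fold, from 34.6 ± 3.12 to 7.47 ± 2.77 CPM (log2 change -2.21, SE 0.32, adjusted p = 2.01e-05; SD, n = 3 each). Nplp2, a neuropeptide-like precursor gene, fell from 315.6 ± 25.3 to 191 ± 30.1 CPM (log2 change -0.73, SE 0.12, adjusted p = 0.00212). The gene of the fly hypoxia-inducible factor alpha subunit, sima, rose from 77.3 ± 8.16 to 141.7 ± 48.9 CPM (log2 change 0.87, SE 0.16, adjusted p = 0.00307). The heat shock co-chaperone gene DnaJ-1 rose from 71.0 ± 6.12 to 119.6 ± 11.4 CPM (0.75, SE 0.14, adjusted p = 0.00269). Cytoplasmic actin Act5C rose by 0.27 (SE 0.05, adjusted p = 0.00269), with its sign kept under TMM, DESeq2's size factors and library totals. In all, 3 genes rose and 11 fell, row included. Among the others that fell were He, which encodes the hemocyte surface protein Hemese (log2 change -1.96), the neprilysin-like gene CG14523 (-0.86) and Glt, which encodes the basement membrane protein glutactin (-0.61). CG1358 (-0.88), CG6310 (-0.54) and the peroxiredoxin gene Prx2540-1 (-0.86, uncertain because near-identical copies exist) fell too. CG3961 (-0.52) and CG1092 (-0.34), chosen after their values were seen, complete the genes that fell, whose adjusted p lay between 2.01e-05 and 0.0484. DESeq2 called 22 genes and 423 had an unadjusted p under 0.05, against 369 by chance.

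Heat shock genes were higher in row RNAi as a list: 11 of 12 measured members lay above 0, with a median log2 change of 0.38 (camera adjusted p = 2.30e-04; adjusted p = 0.388 with an estimated correlation). Of them 1 rose over all genes (DnaJ-1) and 3 adjusted over the list alone. Hsp23 had a log2 change of 0.36 (SE 0.09), Hsp83 0.23 (SE 0.08) and Hsp68 0.56 (SE 0.26). Apoptosis genes were also higher, 9 of 11 above 0 with a median of 0.18 (camera adjusted p = 0.0198; adjusted p = 0.388 with an estimated correlation), with 0 members past the test over all genes and 2 adjusted over the list alone. The initiator caspase gene Dronc had a log2 change of 1.00 (SE 0.28), the stress transcription factor gene Xrp1 0.29 (SE 0.09) and the effector caspase gene Drice 0.29 (SE 0.12). The JNK and stress signalling list had 11 of 16 members above 0 and a median of 0.25 (camera adjusted p = 0.0281; adjusted p = 0.388 with an estimated correlation). Of its members 0 passed over all genes and 1 adjusted over the list alone, with the matrix metalloproteinase gene Mmp1 at 1.39 (SE 0.37) and kay, the fly Fos gene, at 0.33 (SE 0.12). Lamellocyte markers had 5 of 6 above 0 and a median of 0.22 (camera adjusted p = 0.0136; adjusted p = 0.43 with an estimated correlation). Of them 0 passed over all genes and 2 adjusted over the list alone, with the prophenoloxidase gene PPO3 at 0.83 (SE 0.22) and the spectraplakin gene shot at 0.42 (SE 0.13). Their median per library was 0.108 to 0.404 in row RNAi and 0.213 to 0.502 in BEAF-32 RNAi, against at most 0.027 in control, and the test between these dsRNA groups did not pass (camera adjusted p = 0.704). Plasmatocyte markers did not pass as a list (camera adjusted p = 0.413), and 2 of 20 fell over all genes and adjusted over the list alone, He and Glt.

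When 1 library at a time was left out of the row RNAi comparison, 3 of the 14 calls held in every fit (CG15209, Act5C and Nplp2). The count was 4 without control replicate 3, 8 without row RNAi replicate 1, 6 without row RNAi replicate 2 and 7 without row RNAi replicate 3. DnaJ-1 was lost without row RNAi replicate 2 (adjusted p = 0.0534) and sima without that library or control replicate 3 (highest 0.281). He was lost without control replicate 3 or row RNAi replicate 1, 2 or 3 (highest 0.471). CG14523 was lost without control replicate 3 or row RNAi replicate 2 (highest 0.0699). Each of the other lost calls depended on 2 to 6 of the libraries, with a highest adjusted p of 0.48 (CG6310). He also missed the threshold with library totals (adjusted p = 0.0589) and in limma-voom (0.698), and CG6310 in limma-voom (0.0602). CG15209 overlaps sbr and CG32669, He overlaps NimB5 and Glt overlaps CG9287 on the opposite strand, so their counts are uncertain to that extent. The heat shock list held in all 6 fits (highest adjusted p = 0.0345). The apoptosis list was lost without control replicate 3 (0.157) or row RNAi replicate 1 or 3 (0.0504 and 0.0562). The JNK list was lost when any library except control replicate 2 was left out (highest 0.161, without control replicate 3), and the lamellocyte list without control replicate 1 (0.0777) or row RNAi replicate 1 (0.195).

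Double RNAi against control asked what changes in cells given dsRNA against both genes. The largest rises were CG43293 on 3L, from 4.39 ± 0.577 to 20.8 ± 0.962 CPM (4.71-fold; log2 change 2.24, SE 0.41, adjusted p = 0.00212; SD, n = 3 each), and CR44029, a transcript antisense to unc-13, from 4.69 ± 0.519 to 19.1 ± 4.80 CPM (log2 change 2.01, SE 0.43, adjusted p = 0.0121). DnaJ-1 rose by 0.73 (SE 0.14, adjusted p = 0.00238) and shot by 0.63 (SE 0.13, adjusted p = 0.0114). Nplp2 fell from 315.6 ± 25.3 to 150.7 ± 27.6 CPM (2.11-fold; log2 change -1.08, SE 0.12, adjusted p = 8.43e-07) and CG15209 to 11.2 ± 5.05 CPM (log2 change -1.62, SE 0.30, adjusted p = 0.00226). The neighbouring neprilysin-like genes CG14527 (-1.60, SE 0.33) and CG14523 (-1.01, SE 0.16) fell, as did the hexosaminidase gene Hexo1 (-1.20, SE 0.29). CG4210 (-1.14, SE 0.28), CG34232 (-1.01, SE 0.22), CG9328 (-0.93, SE 0.21) and BEAF-32 fell as well, and adjusted p of these genes lay between 2.63e-04 and 0.0427. In all, 4 genes rose and 16 fell, and with library totals 4 rose and 10 fell. Those outside the naming rule, chosen after their values were seen, were Jheh1, a juvenile hormone epoxide hydrolase gene (-0.85), CG11077 (-0.66), CG15093 (-0.65), Glt (-0.64), CG11899 (-0.62), CG3961 (-0.56) and Karl (-0.34). DESeq2 called 30 genes and limma-voom 16, and 637 had an unadjusted p under 0.05, against 369 by chance.

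**Figure D2:**
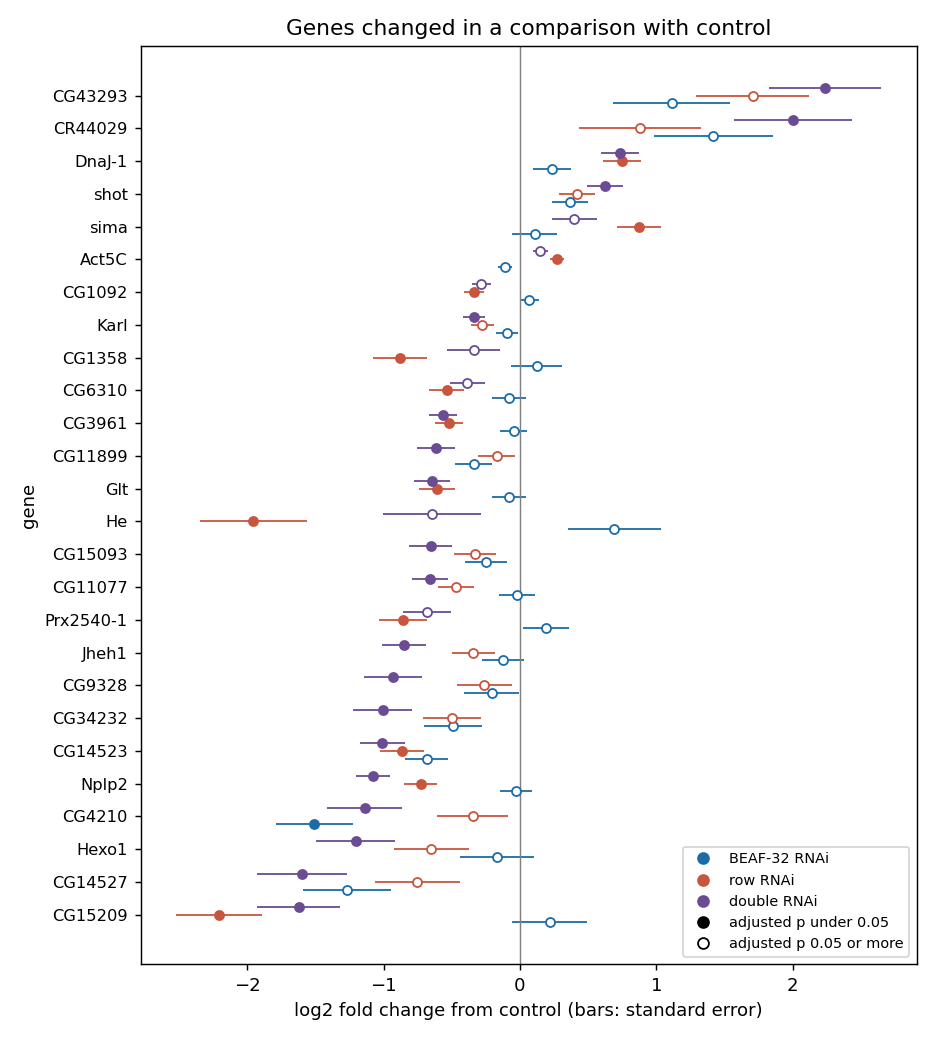
Log2 fold change from control (horizontal axis, bars: standard error) of each gene other than the targets that passed an adjusted p of 0.05 in a comparison with control, in BEAF-32 RNAi, row RNAi and double RNAi (colours), with filled points past the test and open points not. Nplp2 lay at -0.73 in row RNAi and -1.08 in double RNAi, and CG15209 at -2.21 and -1.62.

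The apoptosis, JNK, heat shock and lamellocyte lists were higher in double RNAi by the preset correlation, and none of these calls held with an estimated one. Apoptosis genes had 10 of 11 members above 0 (median 0.26, camera adjusted p = 0.00434; adjusted p = 0.388 with an estimated correlation). Of them 0 passed over all genes and 2 adjusted over the list alone, Xrp1 at 0.30 (SE 0.09) and Dronc at 0.93 (SE 0.29). All 6 measured lamellocyte markers lay above 0 (median 0.38, camera adjusted p = 0.00485; adjusted p = 0.389 with an estimated correlation), 1 called over all genes (shot) and 3 adjusted over the list alone. The lamellocyte list did not pass between double RNAi and BEAF-32 RNAi (camera adjusted p = 0.383). The JNK list had 13 of 16 above 0 (median 0.26, camera adjusted p = 0.00746; adjusted p = 0.388 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone. The JNK phosphatase gene puc lay at 0.67 (SE 0.20), the filamin gene cher, also a lamellocyte marker, at 0.36 (SE 0.11), kay at 0.36 (SE 0.12) and Mmp1 at 1.13 (SE 0.37). Heat shock genes had 10 of 12 above 0 (median 0.22, camera adjusted p = 0.0134; adjusted p = 0.656 with an estimated correlation), 1 over all genes (DnaJ-1) and 3 adjusted over the list alone. Nuclear-encoded respiratory chain genes were lower, 55 of 64 below 0 with a median of -0.11 (camera adjusted p = 0.00128; adjusted p = 0.814 with an estimated correlation). Of them 0 passed over all genes and 3 adjusted over the list alone, ATPsynE at -0.31 (SE 0.09), UQCR-Q at -0.29 (SE 0.08) and ND-B18 at -0.39 (SE 0.11). Cytoplasmic ribosomal protein genes had 80 of 86 below 0 and a median of -0.06 (camera adjusted p = 0.00743; adjusted p = 0.884 with an estimated correlation). Of them 0 passed over all genes and 1 adjusted over the list alone, RpS20 at -0.25 (SE 0.06). Medians of both lists kept their sign under each scaling, and with library totals they were -0.07 for the respiratory chain and -0.03 for ribosomal proteins. Of 20 plasmatocyte markers 1 fell over all genes (Glt) and 2 adjusted over the list alone (camera adjusted p = 0.739 for the list).

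When 1 library was left out of the double RNAi comparison, 5 of the 20 calls held in every fit (Nplp2, CG14523, CG3961, CG43293 and DnaJ-1), and the highest adjusted p of a lost call was 0.404 (CG4210). The count was 9 without control replicate 3, 10 without double RNAi replicate 2 and 12 without double RNAi replicate 3. CG15209 was lost without double RNAi replicate 2 (adjusted p = 0.0548) and shot without that library or control replicate 3 (highest 0.223). CG14527 was lost without control replicate 3 or double RNAi replicate 1 (highest 0.129). CR44029 was lost without control replicate 1, 2 or 3 or double RNAi replicate 2 (highest 0.143). Hexo1, CG4210, CG34232 and CG9328 were lost without 3 to 5 of the libraries. In limma-voom CR44029 (adjusted p = 0.0856) and CG34232 (0.058) missed the threshold, and with library totals Hexo1 (0.0614) and CG4210 (0.0614). CG43293 overlaps D19A and Hexo1 overlaps CG15012 on the opposite strand, so their counts are uncertain, as is that of CR44029. CG14523 and CG14527 both overlap CG33203, on the same and the opposite strand, so their falls may not be separate. All 6 list calls were lost without double RNAi replicate 3, the deepest library, which had the lowest share of counts from ribosomal protein genes (38.4%). Their adjusted p was then 0.0941 for apoptosis and JNK, 0.0584 for lamellocyte markers, 0.0616 for heat shock, 0.31 for the respiratory chain and 0.644 for ribosomal proteins. Without control replicate 1, which had the highest such share (42.1%), the ribosomal protein list had 0.749 and the heat shock list 0.394. Without control replicate 3 the JNK list had 0.0624. Heat shock genes missed the threshold without double RNAi replicate 3 only after adjustment. Before it, their camera result there was close to those without double RNAi replicate 1 or 2.

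**Figure D3:**
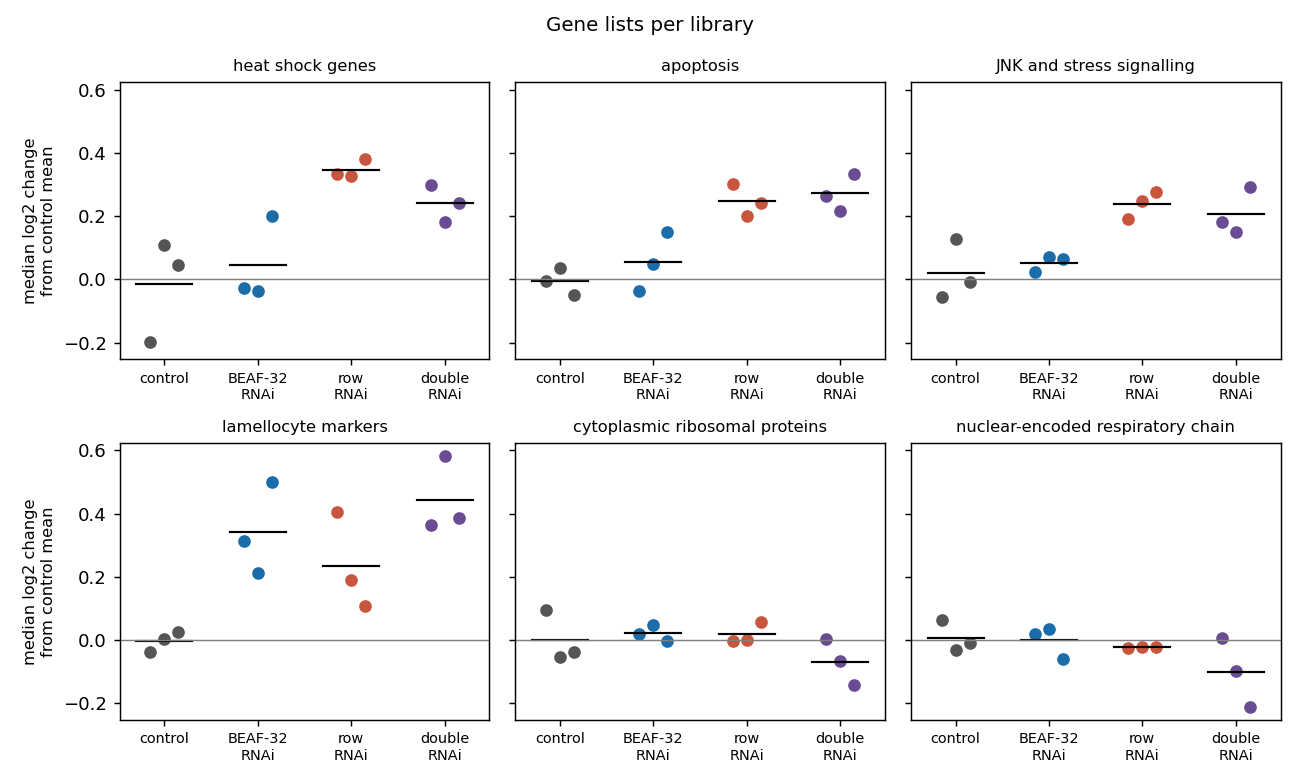
Median log2 change from the control mean (vertical axis) over the members of 6 gene lists, per library (points), with the mean of each group's 3 libraries (black line). The heat shock list had a fitted median of 0.38 in row RNAi and 0.22 in double RNAi against control, and the ribosomal protein list -0.06 in double RNAi.

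The comparisons with control shared some of their genes. Row RNAi and double RNAi shared 6 calls, with DnaJ-1 higher and CG15209, Nplp2, Glt, CG3961 and CG14523 lower in each. Independent lists would share 0.00163 higher and 0.0239 lower. Unchanged groups simulated with 1 set of simulated controls in common shared 0.025 on average (at most 1 in 40 simulations). Both references are low by construction. Independent lists leave out the shared controls, and the simulations held no changed gene and drew each gene independently. They therefore do not test the number shared. BEAF-32 RNAi and double RNAi shared 2, BEAF-32 and CG4210, both lower (0.00434 by independent lists and 0 in simulations). BEAF-32 was the dsRNA target in both groups, so only CG4210 was shared beyond the treatment itself. BEAF-32 RNAi and row RNAi shared 0 of their edgeR calls, so no gene was called in all 3 comparisons. At an unadjusted p under 0.05 these comparisons had 382 and 423 genes, and DESeq2 called 2 and 22. Across genes, which are not independent replicates, log2 changes correlated at 0.549 between row RNAi and double RNAi, 0.491 between BEAF-32 RNAi and double RNAi and 0.435 between BEAF-32 RNAi and row RNAi. Simulated unchanged groups gave 0.500, 0.501 and 0.503. The covariances were 0.0938, 0.0801 and 0.0680 against 0.0559, 0.0563 and 0.0560 in simulations, differences of 0.0379, 0.0238 and 0.0121. On log-CPM values, with the part due to the controls estimated from their spread (0.0576), the differences were 0.0158, 0.00618 and -0.00401, so the sign for BEAF-32 RNAi with row RNAi depends on the estimate. The 3 controls could not be split into sets of at least 2 libraries, so part of the excess may come from the shared controls.

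Double RNAi against BEAF-32 RNAi asked what row dsRNA adds. The row transcript itself did not pass here (log2 change -0.43, SE 0.22, adjusted p = 0.676). BEAF-32 averaged 29.9 CPM in double RNAi and 21.0 in BEAF-32 RNAi, without passing (log2 change 0.51, SE 0.23, adjusted p = 0.569). The groups may thus differ in the lowering of BEAF-32 as well as in row dsRNA. Nplp2 (log2 change -1.05, SE 0.12, adjusted p = 1.69e-06) and CG15209 (-1.84, SE 0.30, adjusted p = 3.45e-04) fell. CG5254 (-1.81, SE 0.41, adjusted p = 0.0358) and Prx2540-1 (-0.87, SE 0.18, adjusted p = 0.00926) also fell, and Act5C rose (0.26, SE 0.05, adjusted p = 0.00926), its sign kept under each scaling. In all 1 gene was higher and 8 lower, and 562 had an unadjusted p under 0.05. The split was 3 higher and 10 lower with DESeq2's size factors in edgeR, and 11 higher and 8 lower with library totals alone. Ribosomal protein genes were lower, 77 of 86 below 0 with a median of -0.09 (camera adjusted p = 2.30e-04; adjusted p = 0.84 with an estimated correlation). Of them 0 passed over all genes, and 1 was higher and 8 lower adjusted over the list alone. Respiratory chain genes were lower, 53 of 64 below 0 with a median of -0.10 (camera adjusted p = 4.11e-04; adjusted p = 0.786 with an estimated correlation). Apoptosis genes were higher, 9 of 11 above 0 with a median of 0.24 (camera adjusted p = 0.00821; adjusted p = 0.388 with an estimated correlation). JNK genes were higher, 14 of 16 above 0 with a median of 0.15 (camera adjusted p = 0.0085; adjusted p = 0.388 with an estimated correlation). Heat shock genes were higher, 8 of 12 above 0 with a median of 0.14 (camera adjusted p = 0.0216; adjusted p = 0.656 with an estimated correlation). In each of these 4 lists 0 members passed over all genes, and adjusted over the list alone 1 respiratory chain, 1 apoptosis, 0 JNK and 3 heat shock genes did. With library totals the medians were -0.05 for ribosomal proteins and -0.06 for the respiratory chain. All 5 list calls were lost without double RNAi replicate 3 (adjusted p = 0.0616 to 0.201), and apoptosis (0.0852) and heat shock (0.353) without BEAF-32 RNAi replicate 1. CG15209 and Nplp2 held in every fit with 1 library left out. Act5C was lost without BEAF-32 RNAi or double RNAi replicate 3 (highest adjusted p = 0.279), Prx2540-1 without BEAF-32 RNAi replicate 1 or 2 or double RNAi replicate 3 (0.189), and CG5254 when any of the 6 except BEAF-32 RNAi replicate 1 was left out (0.279). The count was 4 without double RNAi replicate 3, 24 without double RNAi replicate 1 and 14 without BEAF-32 RNAi replicate 1.

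Double RNAi against row RNAi asked what BEAF-32 dsRNA adds. Row averaged 31.4 CPM in double RNAi and 26.2 in row RNAi, without passing (log2 change 0.25, SE 0.23, adjusted p = 0.935). BEAF-32 had the smallest adjusted p (0.211, log2 change -0.98, SE 0.22), and 0 genes passed edgeR's test, DESeq2's or limma-voom's, with 458 at an unadjusted p under 0.05 against 369 by chance. Ribosomal protein genes were lower (77 of 86 below 0, median -0.09, camera adjusted p = 1.07e-04; adjusted p = 0.84 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone. Respiratory chain genes were also lower (51 of 64 below 0, median -0.08, camera adjusted p = 0.029; adjusted p = 0.84 with an estimated correlation), 0 over all genes and 0 adjusted over the list alone. With library totals the medians were -0.04 and -0.03. Without double RNAi replicate 3 these lists had adjusted p = 0.178 and 0.779. The respiratory chain list was also lost without row RNAi replicate 2 (0.0513) or 3 (0.171) or double RNAi replicate 2 (0.061). In this comparison 1 gene passed without row RNAi replicate 1 or double RNAi replicate 1, and 2 without double RNAi replicate 3.

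Row RNAi against BEAF-32 RNAi compared the single depletions directly. The row transcript itself did not pass in this comparison (log2 change -0.68, SE 0.22, adjusted p = 0.276). He (log2 change -2.65, SE 0.39, adjusted p = 0.00185) and CG15209 (-2.43, SE 0.31, adjusted p = 1.22e-06) were lower in row RNAi. CG11825 (-1.38, SE 0.33, adjusted p = 0.0344) and CR43957, antisense to ci (-1.18, SE 0.27, adjusted p = 0.0277), were lower as well. BEAF-32 (1.49, SE 0.22, adjusted p = 2.18e-05) and the inducible chaperone gene Hsp68 (1.21, SE 0.27, adjusted p = 0.0182) were higher. CG4210 (1.16, SE 0.28, adjusted p = 0.0403) and sima (0.76, SE 0.16, adjusted p = 0.0159) were higher too. In all 11 genes were higher and 14 lower, with 543 at an unadjusted p under 0.05 and 32 called by DESeq2. Heat shock genes were higher (10 of 12 above 0, median 0.25, camera adjusted p = 0.00129; adjusted p = 0.389 with an estimated correlation), 1 over all genes (Hsp68) and 3 adjusted over the list alone. This list held in all 6 fits with 1 library left out (highest adjusted p = 0.0445). Of the 25 genes 7 held in every such fit (CG15209, Act5C, BEAF-32, Prx2540-1, Cbs, Nplp2 and CG1092). He was lost without row RNAi replicate 1, 2 or 3 (highest adjusted p = 0.0952) and in limma-voom (0.263), and CG11825 and CR43957 whichever of the 6 libraries was left out (highest 0.167 and 0.288). Hsp68 was lost without BEAF-32 RNAi replicate 1 or row RNAi replicate 2 (highest 0.203), and sima without BEAF-32 RNAi replicate 1 or 3 or row RNAi replicate 2 (highest 0.495). CG4210 was lost without BEAF-32 RNAi or row RNAi replicate 1 or 3 (highest 0.285). In limma-voom CG11825 (adjusted p = 0.0832), CG4210 (0.0786) and sima (0.0937) missed the threshold, as they did with only the groups compared (0.0571, 0.0862 and 0.131). The count was 13 without BEAF-32 RNAi replicate 3, 16 without row RNAi replicate 1, 8 without row RNAi replicate 2 and 13 without row RNAi replicate 3.

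The interaction asked whether the log2 change in double RNAi departs from the sum of the changes in the single depletions. Each target averaged higher in double RNAi than in its single depletion, without passing. The depletions that are summed may therefore differ from those in double RNAi. For row itself the departure was 0.52 (adjusted p = 1) and for BEAF-32 0.46 (adjusted p = 1). In edgeR, DESeq2 and limma-voom 0 genes passed, with 326 at an unadjusted p under 0.05 against 369 by chance and a smallest adjusted p of 0.512. Ribosomal protein genes were lower than the sum as a list, 76 of 86 below 0 with a median of -0.11 (camera adjusted p = 2.30e-04; adjusted p = 0.84 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. With library totals the median was -0.06. Without double RNAi replicate 3 the adjusted p of the list was 0.0941.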

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

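The tests of dsRNA exposure for heat shock genes and for CG14523, the tests of single libraries for heat shock genes in double RNAi, the abundance test of respiratory chain genes and the comparison with the spread between libraries were chosen only after the result was seen. Thinning in double RNAi and the length trend of respiratory chain genes had no prediction set in advance. The others were planned.

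Cytoplasmic ribosomal protein genes lay below the sum of the single changes in double RNAi by the preset correlation: their median interaction was -0.11, and -0.06 with library totals (camera adjusted p = 2.30e-04; adjusted p = 0.84 with an estimated correlation). The call was also lost without double RNAi replicate 3 (adjusted p = 0.0941).

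Ribosomal protein and respiratory chain genes were lower in double RNAi than in control by the preset correlation, but not with an estimated one (adjusted p = 0.884 and 0.814 with an estimated correlation). The ribosomal protein shift goes with single libraries: its unadjusted camera p was 0.366 without control replicate 1 and 0.23 without double RNAi replicate 3, and double RNAi replicate 1 (0.00415) lay above control replicates 2 and 3 (-0.0528 and -0.0368). Removing the trend with annotated transcript length moved the ribosomal protein median from -0.06 to -0.0194 (bootstrap over genes -0.0325 to -0.0108) and the respiratory chain median from -0.11 to -0.0646 (-0.110 to -0.0362). The medians lay below 97.76% and 100% of draws meant to match abundance, but only 8 genes outside both lists are as abundant as the median ribosomal protein gene, so the draws for that list are not matched. Resampling genes leaves out the spread between libraries (SE of the medians 0.0631 and 0.0696), and the values left were not large against it, so length, abundance and a response to the double depletion cannot be told apart.

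Heat shock genes were higher in row RNAi and double RNAi than in control by the preset correlation, but not with an estimated one (adjusted p = 0.388 and 0.656 with an estimated correlation). Row RNAi lay above BEAF-32 RNAi (unadjusted camera p = 0.025 with the correlation estimated, and 0.389 after adjustment). For double RNAi against BEAF-32 RNAi the unadjusted camera p was 0.0703. Neither value decides on exposure to dsRNA of any sequence. No cells received unrelated dsRNA, and a gap between dsRNA groups can also come from members lowered in BEAF-32 RNAi. Hsp68 averaged 16.5 ± 6.45 CPM in BEAF-32 RNAi and 26.2 ± 3.75 in control, and DnaJ-1 83.7 ± 5.20 and 71.0 ± 6.12. Neither gene passed between these groups (DnaJ-1 log2 change 0.23, SE 0.14, adjusted p = 0.937). With the preset correlation, the highest unadjusted camera p in row RNAi with 1 library left out was 0.00264. By that test the shift in row RNAi did not rest on a single library. In double RNAi the highest was 0.00306 with 1 double RNAi library left out. The list did not pass with an estimated correlation, so these fits do not exclude an artefact of the libraries. After adjustment, though, that fit, without double RNAi replicate 3, missed the threshold (camera adjusted p = 0.0616). The shift in double RNAi also depends on control replicate 1, the lowest library (-0.198), without which the unadjusted camera p was 0.0764. After thinning every library to 2276507 counts the unadjusted camera p of the list was 1.27e-05 in row RNAi and 0.00152 in double RNAi. These values too used the preset correlation. Mean totals were already close before thinning (3091040 in row RNAi, 2859500 in double RNAi and 2910000 in control), so thinning decides little about depth. In row RNAi a response to row depletion may be proposed, only as a hypothesis found and tested on the same libraries. Exposure to dsRNA stays open beside it, and an effect of this row dsRNA on another transcript was not tested.

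CG14523 averaged 111.8 CPM in control and 69.2, 61.2 and 55.6 in BEAF-32, row and double RNAi, and BEAF-32 RNAi against control did not pass (log2 change -0.68, adjusted p = 0.18). Its smallest adjusted p between dsRNA groups was 0.68. A response to dsRNA itself and responses to each depletion cannot be told apart, because no cells received unrelated dsRNA. CG14523 also overlaps CG33203 on the same strand.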

How the results depend on the processing

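All alternatives were planned and none was chosen only after the result was seen. No call reversed under any of them. A result called in neither fit was counted as held whatever its sign. For example, BEAF-32 in row RNAi against control went from 0.05 to -0.12 without control replicate 2. Of the 48 results on named genes, all 48 kept their side of the threshold, and the called ones their direction, with DESeq2's size factors, CPM of at least 10 and no filter. In DESeq2 47 did (CG5254 had no adjusted p there). In the same sense 44 held with only the groups compared, 43 with library totals and 39 in limma-voom. With 1 library left out, 173 of 288 did. Of 20 list calls, 20 held with DESeq2's size factors, 0 with an estimated correlation, 0 in fry, and 92 of 126 with 1 library left out. Counts of calls moved as follows, and the cause was not tested. DESeq2 called 22 genes in row RNAi against control (all 14 of the main test among them) and 24 in double RNAi against BEAF-32 RNAi, where library totals gave 19, no filter 23 and limma-voom 18, against 9. Double RNAi against row RNAi had 3 calls with no filter and 2 with only the groups compared, against 0. Row RNAi against BEAF-32 RNAi had 54 with no filter, against 25. At a threshold of 0.01, which is stricter by construction, 8 genes passed in row RNAi against control, 10 in double RNAi against control, 9 in row RNAi against BEAF-32 RNAi, and 0 were shared by BEAF-32 RNAi and double RNAi against control. BEAF-32 in double RNAi against control had a log2 change of -0.89 with library totals (adjusted p = 0.0604) and -0.89 in limma-voom (0.0512). Leaving out 1 library gave 1 to 4 calls in BEAF-32 RNAi against control, 4 to 13 in row RNAi, 9 to 23 in double RNAi. It gave 4 to 24 in double RNAi against BEAF-32 RNAi, 0 to 2 in double RNAi against row RNAi, 8 to 21 in row RNAi against BEAF-32 RNAi and 0 to 0 for the interaction. Log2 changes of the targets then ran from -1.15 to -0.85 (row in row RNAi), -1.10 to -0.81 (BEAF-32 in double RNAi), -0.79 to -0.56 (row in double RNAi) and -1.62 to -1.24 (BEAF-32 in BEAF-32 RNAi).

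Libraries with the same replicate number did not deviate together: over 18 pairs the correlation of deviations from the group means ran from -0.117 to 0.0617, with 0 pairs over 0.1, and 5 of 12 libraries correlated best with their own number. No pairing by number was thus detected, which does not exclude one, since the labels give only a number. With the replicate block, row RNAi against BEAF-32 RNAi had 16 calls, all among the 25, BEAF-32 RNAi and double RNAi shared 1 gene, 42 of 48 results on named genes held, and 19 of 20 list calls held, the exception being the respiratory chain in double RNAi against row RNAi. Depth limits small changes: for genes of at least 50 CPM, 100% of simulated 2-fold changes were recovered in BEAF-32 RNAi against control and 77.8% of 1.5-fold ones, while over all genes 64% and 34% were. That simulation had 101 calls against 2 in the real comparison, so these shares overstate recovery there.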

Other observations

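The test of neighbouring genes was chosen only after the result was seen; the others were planned.

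Several lists tied to the biology of the study did not pass the test. The 7 measured partners of the HP1c complex, of which ROW is part, all lay below 0 in BEAF-32 RNAi and in double RNAi, with medians of -0.14 and -0.13 (camera adjusted p = 0.354 and 0.19), and had a median of -0.06 in row RNAi (0.952). In double RNAi against row RNAi 2 of them were lower adjusted over the list alone and 0 over all genes (list adjusted p = 0.239). The 24 insulator and architectural protein genes had medians of -0.01, 0.02 and -0.02 in BEAF-32, row and double RNAi (adjusted p = 0.704, 0.989 and 0.845). Dref, a factor that binds sites related to those of BEAF-32, had a log2 change of -0.73 (SE 0.20, adjusted p = 0.103) in double RNAi, the 1 member past the test adjusted over the list alone, against 0 over all genes. RNA interference and antiviral genes had medians of 0.02, 0.06 and 0.05 (adjusted p = 0.888, 0.704 and 0.636), and antimicrobial and immune effectors 0.12, 0.18 and 0.21 (0.262, 0.36 and 0.095). Per library the median of the latter lay at 0.0804 to 0.368 in the 9 dsRNA libraries and at -0.207 to 0.0502 in the 3 controls. Chromatin modifiers had medians of -0.07, -0.01 and 0.09 (0.261, 0.637 and 0.765). Of the 28 lists 21 passed in no comparison. The smallest adjusted p among these was 0.0632, for proteasome subunits in double RNAi against row RNAi.

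Genes with a nearest upstream neighbour transcribed away from them, an arrangement common near BEAF-32 sites, were tested as a class in BEAF-32 RNAi. The class was set by gene order and strand alone, with no limit on distance and no data on BEAF-32 sites. It therefore could not single out close pairs of genes bound by BEAF-32. The 4475 such genes of 7023 had a median log2 change of -0.00194, against -0.00167 for the others (unadjusted camera p = 0.181 with the correlation estimated). The bound set in advance, a p of 0.05 or more, does not exclude an effect on the class, since members that move both ways leave its median near 0, so the question stays open. Among the 42 called genes 2 pairs were adjacent or next but 1, CG14523 with CG14527 and CG11825 with Prx2540-1. CG14523 and CG14527 both overlap CG33203, so that pair may share counts. Random sets of tested genes gave 0.301 pairs on average, and 358 of 10000 random sets held as many pairs. The bound set for the test, more pairs than the upper percentile of the random sets (2), was not passed, and 2 pairs are too few to decide.

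Other splits of the same libraries were counted for each comparison. In each comparison of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05. The real split and the highest other split called 2 and 2 genes for BEAF-32 RNAi against control, 14 and 0 for row RNAi, 20 and 0 for double RNAi, 9 and 10 for double RNAi against BEAF-32 RNAi, 0 and 1 for double RNAi against row RNAi, and 25 and 0 for row RNAi against BEAF-32 RNAi. For the interaction the real count was 0, which each of the 100 assignments drawn reaches by definition, so the count decides nothing. The highest other called 11, and such assignments also mix libraries of groups that differ.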
